A study of Mus musculus with 4 samples.

How the data were processed

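RNA from colon of Balb/c mice was hybridised to GeneChip Mouse Gene 2.0 ST arrays, on which a probe set (transcript cluster) sums probes spread over the exons of a gene. The labels describe 2 control arrays (numbered 1 and 2, plain drinking water) and 2 maltodextrin arrays (numbered 3 and 4, 5% maltodextrin in the drinking water), all after 45 days. Each sample was put in its group by its label. The labels give the sample numbers as 1 series through both groups, so no pairing was used. The labels do not say whether the samples of a group came from separate mice, so single-gene p-values measure only the spread between these samples, which may be technical. With 2 arrays per group the smallest two-sided p of an exact permutation test is 0.333, so no single-gene permutation test was made.

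The deposited value table holds log2 intensities for 41345 probe sets, from about 2 to about 14 on each array. The array medians were 5.35, 5.22, 5.20 and 5.24 in the order control 1, control 2, maltodextrin 3, maltodextrin 4. Partek 6.6 is named in the submitters' processing notes. The background correction, normalization and summarization are not given in the sources used here. The authors' deposited table of comparisons has 33793 rows, with a ratio, a signed fold, a p-value and a step-up p-value per row, per the file headers. Its log2 ratio differed from the difference of group means in the value table by at most 8.9e-05, and its p-value from that of an equal-variance test on the same values by at most 0.00064, so that test is called the methods' t-test here. A deposited list holds the 1677 rows with a fold of at least 1.5 and an unadjusted p under 0.05, a criterion checked on the rows. In the list 17 fold cells differed from the comparison table and 1 gene symbol had turned into a date, so folds were taken from the comparison table.

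Gene symbols came from the deposited comparison table. Of the value table rows, 32202 had a symbol (30861 distinct), 1591 rows of the comparison table had none, and 7552 rows were in the value table alone. Of the distinct symbols, 25451 (82.5%) were current symbols in the reference gene table (GRCm38.p6). Older symbols of the file were kept, such as Emr1 for Adgre1, Igj for Jchain and Faim3 for Fcmr. Gene positions are those of the reference gene table. Of 770 genes with over 1 probe set, 39 had a probe set past the nominal criterion and differences of both signs. 4338 of the named probe sets can match several transcripts, per the file headers.

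The 32202 named probe sets were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, maltodextrin minus control, two-sided, with Benjamini-Hochberg adjustment. The fit had 2 residual degrees of freedom and a prior of 2.62. A fold of at least 1.5 with an unadjusted p under 0.05 is a nominal criterion and is always named so. Gene lists (40 lists, 760 entries, 737 of them measured) were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, taking for each gene the probe set with the highest mean. At the preset correlation camera sets a list's genes against all other genes. Its small p-values rest on the number of genes and not on the number of samples or mice. The test was also run with an estimated correlation and with fry, a rotation test of whether a list's genes move one way on balance. Members were also adjusted over the list alone. Genes to be named were fixed in the same way: the 12 largest differences each way among those at the nominal criterion with both maltodextrin arrays on the same side of both control arrays (2564 candidates, 2274 of them higher), since fewer than 24 passed the adjusted threshold, then 12 genes of endoplasmic reticulum stress and mucus, and up to 4 members with the largest differences in each list. Predicted genes and clone names (Gm, Rik, LOC, BC and AU names), small nucleolar and Cajal body RNAs with Snor and Scarna names, 5S ribosomal RNAs (n-R names), microRNAs, receptor families and antigen receptor segments were set aside from the largest differences, and the main ones counted as classes instead. Other names were chosen after the values were seen and are given as such. A few genes that these rules name are not reported here.

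The alternatives fixed before the data were examined were a mean log2 of at least 5, quantile normalization applied again, arrays centred on their medians, all rows of the value table, eBayes with trend and robust settings, the methods' t-test, each array left out in turn, a fold of at least 2, the authors' deposited fold and p-values, the mean of all probe sets of a gene, and both other list tests. Probe sets that match 1 place only, and control 1 against maltodextrin 4 alone, were added after the data were seen. For the list tests, eBayes with trend and robust settings repeats the main fit, since camera does not use those settings. The number of arrays limits the precision. As a guide to signal over background, the 95th percentile of the mean log2 intensity of olfactory and vomeronasal receptor probe sets was 5.43.

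The fit was tested on simulated data for the 32202 probe sets of the maltodextrin comparison, with 200 changed. At a fold of 2, adjusted p-values recovered 0 of the 200 and the nominal criterion 183, with 984 unchanged probe sets also past the nominal criterion. At a fold of 4, adjusted p-values recovered 181 of the 200, with 12 false calls. In 20 simulated data sets with no effect, camera called 4 of 800 lists. With the endoplasmic reticulum stress list shifted by 0.5 on the log2 scale it called that list in 20 of 20 with the preset correlation and in 0 of 20 with the estimated one. With the goblet cell or macrophage list shifted by 0.9, or the plasma cell list by 1.2, the counts were also 20 and 0 of 20 for each. Camera with an estimated correlation thus called no shift of these sizes. A list that does not pass it is therefore not shown to be unshifted. Genes vary independently in these simulations. Figures were drawn with matplotlib 3.10.9.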

Results

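Gene expression in mouse colon was measured after 45 days of plain drinking water (control, 2 arrays) or of drinking water with 5% maltodextrin (2 arrays). Maltodextrin is a starch-derived polysaccharide used as a food additive, and the comparison asked how it alters colonic expression, with endoplasmic reticulum (ER) stress and mucus as a known interest of the study. Each array gave a log2 intensity for 41345 probe sets, of which 32202 carry a gene symbol. Differences are maltodextrin minus control on the log2 scale, and errors are SD over 2 arrays unless given as SE.

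Outside the classes counted separately, the genes highest on the maltodextrin arrays included products of mast cells. Mcpt1, a mucosal mast cell protease, was higher by 3.59 (SE 1.04), Mcpt2 by 3.06 (SE 0.84) and Cpa3, mast cell carboxypeptidase, by 3.50 (SE 0.39). Retnlg, a resistin-like molecule of neutrophils, was higher by 3.22 (SE 0.43), and Tnfrsf17, the plasma cell receptor for BAFF and APRIL, by 2.61 (SE 0.55). Metabolic and transport genes in the same set were Slc13a1, a sodium and sulfate cotransporter, at 3.51 (SE 1.17) and Hpd, an enzyme of tyrosine breakdown, at 2.69 (SE 0.19). Creb3l4, a membrane-bound transcription factor of the ER, was higher by 2.86 (SE 0.17), with 6.78 ± 0.03 (SD, n = 2) in control and 9.64 ± 0.02 (SD, n = 2) in maltodextrin. A4gnt, a glycosyltransferase of mucin O-glycans, was higher by 3.06 (SE 0.28). Arhgap20 at 3.06 (SE 0.98) and Vsig2 at 2.53 (SE 0.61) were also in the set. Sizes depended on single arrays: with 1 array left out the difference ranged from 1.80 to 5.23 for Slc13a1, 2.21 to 4.97 for Mcpt1, 1.81 to 4.32 for Mcpt2, 1.61 to 4.50 for Arhgap20 and 1.66 to 3.40 for Vsig2, each larger on maltodextrin 3 (Slc13a1 10.65 against 7.22 on maltodextrin 4), but from 2.84 to 2.88 for Creb3l4. The control means of these 5 genes and of Cpa3, Retnlg and Tnfrsf17, from 3.76 to 5.42, lay below 5.43, the 95th percentile of the receptor probe sets, so these differences are measured from near background.

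Outside the classes set aside by name, the largest differences in the other direction were those of Amy2a5, pancreatic amylase, at -4.08 (SE 1.39), and Atp12a, the colonic proton and potassium pump, at -3.55 (SE 1.22). Short noncoding RNAs made up 7 of the 12: the U3 RNAs Rnu3a at -3.51 and Rnu3b4 at -2.44, small nucleolar RNAs whose names kept them out of that class, the U1 RNA Rnu1b1 at -3.46 (-2.27 without control 2), the RNase P RNA Rpph1 at -2.24, and the mitochondrial tRNAs mt-Th at -2.29, mt-Tn at -1.97 and mt-Te at -1.86. The others were Atg16l1, an autophagy gene, at -2.67 (SE 0.58; -1.83 without control 2 and -3.52 without control 1), Tnnt2, a troponin, at -2.03 (SE 0.56; -1.33 without maltodextrin 3), and S100a14 at -1.85 (SE 0.36). Atg16l1 was 8.09 and 9.79 on control 1 and control 2, and 6.18 and 6.36 on maltodextrin 3 and maltodextrin 4. Control 2 was also the highest array for the small nucleolar RNA class (median 9.76). Whether this probe set measures Atg16l1 mRNA was not tested. Amy2a5 was set apart by 1 array, with 11.76 on control 2 against 7.58 on control 1 (difference -1.99 without control 2 and -6.17 without control 1). Atp12a was 6.71 on maltodextrin 3 and 10.36 on maltodextrin 4, both below the controls (difference -1.72 without maltodextrin 3 and -5.38 without maltodextrin 4).

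No probe set of the 32202 passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 0.191. By the methods' t-test the count was also 0. At an unadjusted p under 0.05 limma gave 4698 probe sets, where 1610 would be given by chance alone. The nominal criterion was met by 3887 probe sets, 2739 higher and 1148 lower. Both other splits of the 4 arrays into 2 and 2 gave 285 and 437. These splits mix controls with maltodextrin arrays, so any difference between the groups enters the spread and lowers their counts. They are therefore no baseline for 3887. The number turned on single arrays: 6369 without control 1, 6894 without control 2, 1288 without maltodextrin 3 and 1949 without maltodextrin 4. The excess of higher over lower turned around without control 2, with 2991 higher and 3903 lower. Without control 1 or control 2, 905 and 671 probe sets passed the adjusted threshold, where the spread comes from the maltodextrin pair alone and the lone control is assumed to vary like it. The maltodextrin arrays correlated at 0.984 across probe sets and the controls at 0.9504, below the 0.957 and 0.952 of control 1 and control 2 with maltodextrin 4. Log2 intensities had an SD of 2.21 and 2.20 on the maltodextrin arrays, against 2.06 and 2.12 on the controls. The excess of higher depended on brightness. It was 70.5% of the nominal probe sets, and 81.5% with a mean log2 of at least 5. The median difference of all probe sets tested was -0.037 and 0.144 in these settings. Camera compares a list with all other genes, dim ones included, so this shift can enter the list results below.

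Among the ER stress and mucus genes, the clearest difference was in Ern2, the IRE1 beta sensor of ER stress of the mucus-secreting epithelium. It was higher by 1.34 (SE 0.20), with 8.75 ± 0.22 (SD, n = 2) in control and 10.09 ± 0.07 (SD, n = 2) in maltodextrin, which is 2.53-fold. Xbp1, the transcription factor whose mRNA IRE1 splices, was higher by 1.11 (SE 0.20), Spdef, a transcription factor of goblet cells, by 1.09 (SE 0.27), Tff3, the goblet cell trefoil peptide, by 0.79 (SE 0.22), and Agr2, a disulphide isomerase needed for mucin folding, by 0.63 (SE 0.22). These 5 of the 12 genes had an unadjusted p under 0.05 by limma, with adjusted p-values of 0.232 for Ern2 and 0.323 for Agr2, where Muc2 was counted by its brighter probe set and its dimmer one also had an unadjusted p under 0.05. Muc2, the gel-forming mucin of the colon, was 0.51 (SE 0.22) and 0.63 (SE 0.24) higher on its pair of probe sets, with limma adjusted p-values of 0.384 and 0.342, and the brighter one was higher by 0.29 without control 2. The dimmer one was also lowest on control 2, with 13.26 and 12.80 on control 1 and control 2 and 13.76 and 13.55 on maltodextrin 3 and maltodextrin 4. The ubiquitous sensor Ern1 was higher by 0.46 (SE 0.26), or by 0.29 without control 2, 0.70 without maltodextrin 3 and 0.21 without maltodextrin 4. The chaperone Hspa5 differed by 0.07 (SE 0.28), Ddit3, the CHOP factor, by -0.14 (SE 0.20), and Atf4 by -0.39 (SE 0.26; from -0.65 without control 1 to -0.14 without control 2), each within about the spread between arrays. Fcgbp differed by 0.16 (SE 0.37), and the probe set that the file names Clca1 lay near background at 4.30 and 4.42. Because the file keeps older symbols, it was not checked that this is the gene now called Clca1. Ern2 (transcript cluster 17495958) is a protein-coding gene on chromosome 7 from 122169893 to 122186239 in GRCm38.p6, Xbp1 (17246967) lies on chromosome 11 from 5520641 to 5525993, and Muc2 (17485019 and 17484991) on chromosome 7 from 141690340 to 141754691.

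**Figure D1:**
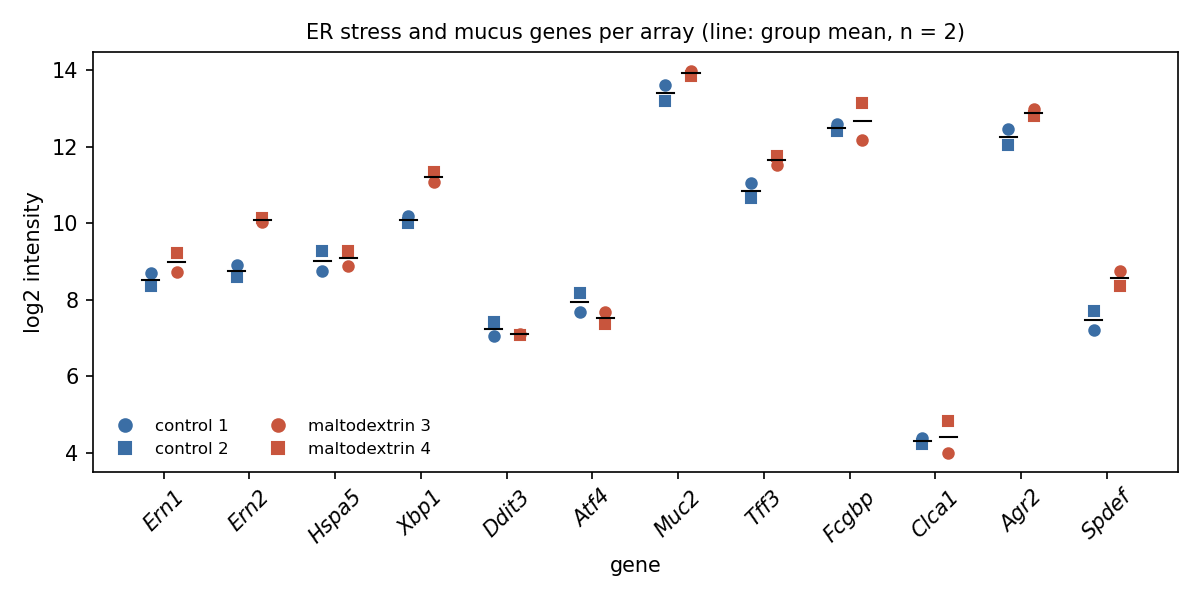
Log2 intensity (y axis) of the 12 ER stress and mucus genes (x axis) on each array, with control arrays in blue, maltodextrin arrays in red and a line at each group mean (n = 2). Both maltodextrin arrays lie above both controls for Ern2 (10.04 and 10.14 against 8.90 and 8.59) and Xbp1, while Hspa5 and Ddit3 overlap.

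The goblet cell and mucus list was higher, with a median of 0.79 over 25 measured members (camera adjusted p = 1.25e-07). With an estimated correlation camera gave an adjusted p = 0.734, in a setting that called 0 of 20 simulated shifts of 0.9 in this list. Of the 25 members, 12 were higher and 1 lower at the nominal criterion and 12 did not meet it. None passed over all genes, and 10 passed when adjusted over the list alone, 9 higher and 1 lower. Atoh1, the transcription factor that sets the secretory lineage, was higher by 2.22, and Rep15, a Rab15 effector, by 1.80. B3gnt6, a core 3 O-glycan synthase, was higher by 2.78 on average, with 9.78 on maltodextrin 3 and 5.16 on maltodextrin 4 (difference 0.47 without maltodextrin 3), and Retnlb was higher by 1.76, with a low value of 9.85 on control 2 (difference 0.27 without control 2).

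The ER stress and unfolded protein response list was also higher, with a median of 0.47 over 33 members (camera adjusted p = 9.45e-06; adjusted p = 0.734 with an estimated correlation). At the nominal criterion 11 were higher and 0 lower, with 0 past the threshold over all genes and 4 adjusted over the list alone. Derl3, a component of ER-associated degradation, was higher by 2.39, Sdf2l1, an ER chaperone cofactor, by 1.34, and Asns, asparagine synthetase, by 1.24, beside Ern2. Xbp1 and Derl3 also stand on the plasma cell list. Control 2 carried pancreatic transcripts, and its values for the chaperones Hspa5 and Hyou1 exceeded those of control 1 by 0.53 and 0.86, while 4 of 13 chaperones and isomerases were lower on control 2, among them Sdf2l1 by 0.77.

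Markers of immune cells moved in both directions. Plasma cell genes were higher, with a median of 1.15 over 12 members (camera adjusted p = 2.57e-05; adjusted p = 0.734 with an estimated correlation), 8 of them higher and 0 lower at the nominal criterion, 0 past over all genes and 4 adjusted over the list alone. Igj, the immunoglobulin joining chain, was higher by 1.60, and Iglc2, a lambda constant segment, by 1.502 (0.83 without control 2). Macrophage and dendritic cell genes were higher, with a median of 0.94 over 19 members (camera adjusted p = 1.25e-07; adjusted p = 0.734 with an estimated correlation), 11 higher and 0 lower at the nominal criterion, 0 over all genes and 11 adjusted over the list alone. Emr1, the macrophage surface protein F4/80, was higher by 2.20, Cd209a by 1.90, and C1qb, a complement chain, by 1.64. B cell genes were lower, with a median of -0.90 over 17 members (camera adjusted p = 0.000498; adjusted p = 0.737 with an estimated correlation), 0 higher and 4 lower at the nominal criterion and 0 adjusted over the list alone. Cr2, complement receptor 2, differed by -1.81 and Ms4a1, CD20, by -1.30 (-0.87 and -0.51 without maltodextrin 3, -2.75 and -2.10 without maltodextrin 4). The B cell median was 6.70 on maltodextrin 3 and 8.09 on maltodextrin 4, and the list was no longer past the threshold without maltodextrin 3 (adjusted p = 0.0724) or without control 1 (adjusted p = 0.0805). Its mean relative to other genes, -0.824, was -0.205 without maltodextrin 3 and -1.44 without maltodextrin 4.

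The neutrophil and mast cell list was higher with a median of 0.32 over 16 members (camera adjusted p = 0.0331; adjusted p = 0.737 with an estimated correlation), 5 of them higher and 0 lower at the nominal criterion and 3 adjusted over the list alone. 12 of its members lay below the 95th percentile of the receptor probe sets, and the list did not pass without control 2 (adjusted p = 0.179) or with a mean log2 of at least 5 (adjusted p = 0.0601), where its mean relative to other genes was larger (1.498 against 0.867) over fewer members. Interferon response genes were lower, with a median of -0.35 over 27 members (camera adjusted p = 0.0331; adjusted p = 0.737 with an estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, differed by -1.33, and the interferon-gamma target Iigp1 was 10.01 on control 1 against 6.86 on control 2. The interferon list's mean relative to other genes, -0.35, was 0.021 without control 1, -0.721 without control 2 and -0.211 without maltodextrin 4, and its call ended without control 1 or maltodextrin 4. T and NK cell genes (median 0.28, adjusted p = 0.0569), MHC class II genes (median -0.23, adjusted p = 0.0873) and inflammatory cytokines (median -0.19, adjusted p = 0.262) did not pass by camera. The MHC class II list did pass in 4 of 11 settings, among them quantile normalization applied again (adjusted p = 0.00751). 14 of the 29 cytokine genes lay below the receptor 95th percentile. Ccl3, a chemokine, was higher by 1.81 from a control mean near background (4.70), or by 1.17 without control 2, and was the only cytokine list member at the nominal criterion.

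Of 6 lists of other epithelial cells and proliferation, 4 were higher past the camera threshold with the preset correlation. None of the 4 passed with an estimated correlation, which also called no simulated list shift. Enteroendocrine genes had a median of 0.20 over 18 members (camera adjusted p = 0.024; adjusted p = 0.734 with an estimated correlation), with Chga, chromogranin A, higher by 1.85 and Gcg, proglucagon, by 1.63, and 2 members passed when adjusted over the list alone. Tuft cell genes had a median of 0.31 over 13 members (camera adjusted p = 0.00868; adjusted p = 0.734 with an estimated correlation), with Sh2d6 higher by 0.89. Stem and crypt base genes had a median of 0.37 over 15 members, all above 0 (camera adjusted p = 0.00405; adjusted p = 0.734 with an estimated correlation), with Prom1 higher by 1.03 (0.63 without maltodextrin 3) and Ephb2 by 0.84 (0.51 without control 1). Proliferation genes had a median of 0.34 over 25 members (camera adjusted p = 0.0331; adjusted p = 0.737 with an estimated correlation), 0 of them at the nominal criterion. Deep crypt secretory genes did not pass (median 0.35, adjusted p = 0.251), though Kit, a receptor tyrosine kinase, was higher by 1.72. Absorptive colonocyte genes did not pass (adjusted p = 0.641), with Scnn1b, an epithelial sodium channel subunit, higher by 1.77 and Alpi, intestinal alkaline phosphatase, at 10.65 on maltodextrin 3 and 6.66 on maltodextrin 4. Single arrays ended the calls for stem cell genes (without control 1), enteroendocrine genes (without control 1) and tuft cell genes (without control 2 or maltodextrin 4). The means relative to other genes kept their direction. They were 0.333 against 0.42 for stem cell, 0.363 against 0.509 for enteroendocrine, and 0.315 and 0.336 against 0.421 for tuft cell genes. The proliferation call ended without control 2, maltodextrin 3 or maltodextrin 4. Its mean relative to other genes was 0.265 with all arrays, 0.085 without control 2 and 0.446 without control 1. It stayed near the full value without maltodextrin 3 (0.245) and without maltodextrin 4 (0.286). With all 4 arrays kept, a mean log2 of at least 5 ended all 4 of these calls (adjusted p from 0.108 to 0.528), the relative mean being 0.465 against 0.509 for enteroendocrine genes but 0.294 against 0.421 for tuft cell, 0.276 against 0.42 for stem cell and 0.12 against 0.265 for proliferation genes, and quantile normalization applied again those for stem cell (adjusted p = 0.126) and proliferation genes (adjusted p = 0.533). Uniquely hybridising probe sets alone also ended the proliferation call (adjusted p = 0.0595), with a relative mean of 0.226 against 0.265.

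**Figure D2:**
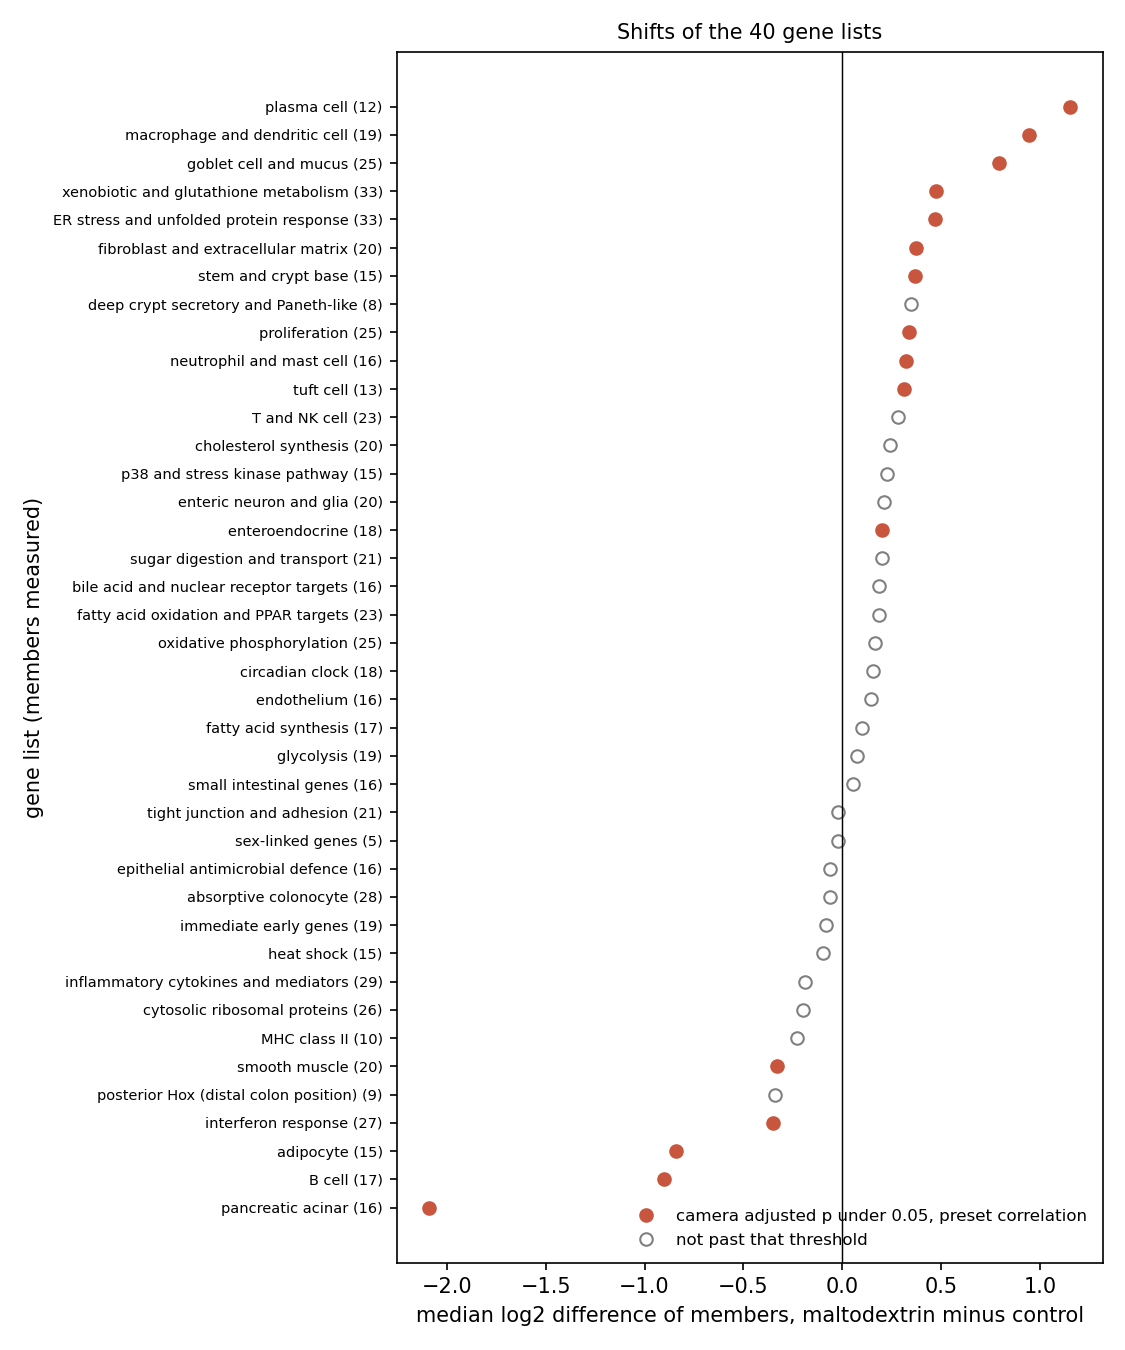
Median log2 difference, maltodextrin minus control (x axis), of the measured members of each of the 40 gene lists (y axis, number measured in brackets). Filled points mark the 16 lists past the camera threshold with the preset correlation, from pancreatic acinar at -2.09 to plasma cell at 1.15, and open points the others.

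Xenobiotic and glutathione genes were higher with a median of 0.47 over 33 members (camera adjusted p = 0.00253; adjusted p = 0.737 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, was higher by 1.23, while Cyp2c65 and Ces1g were 9.64 and 10.09 on maltodextrin 3 but 5.08 and 5.69 on maltodextrin 4. The list did not pass without control 1 or with a mean log2 of at least 5 (adjusted p = 0.0824), and its mean relative to other genes, 0.537, was 0.499 in that last setting, 0.205 without maltodextrin 3 and 0.87 without maltodextrin 4. Fibroblast and matrix genes were higher with a median of 0.37 over 20 members (camera adjusted p = 0.024; adjusted p = 0.737 with an estimated correlation), 5 of them adjusted over the list alone, led by Mmp2, a gelatinase, at 1.45. That call was lost without control 1 or maltodextrin 4, with a mean log2 of at least 5 (adjusted p = 0.52), and with quantile normalization applied again (adjusted p = 0.255), and the list's mean relative to other genes, 0.244, was 0.037 without control 1, 0.451 without control 2, and 0.073 and 0.098 in those last settings. Smooth muscle genes were lower (median -0.33, camera adjusted p = 0.024), as were adipocyte genes (median -0.84, camera adjusted p = 0.0336), each with an adjusted p = 0.737 with an estimated correlation and each lost without control 2 or maltodextrin 4. Relative to other genes the smooth muscle mean, -0.339, ranged from -0.619 without maltodextrin 3 to -0.059 without maltodextrin 4, and the adipocyte mean, -0.721, from -1.26 to -0.178 in the same settings. Without control 1 they were -0.534 and -1.198, and without control 2 they were -0.143 and -0.244. Myh11, smooth muscle myosin, differed by -0.91 (-0.42 without control 2) and Retn, resistin, by -1.55 (-0.74 without maltodextrin 4).

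Lists of sugar, lipid and energy metabolism did not pass by camera with all 4 arrays. Sugar digestion and transport had a median of 0.20 (adjusted p = 0.0569), with Slc2a5, the fructose transporter, higher by 0.97 and Fbp1 by 1.13. The relative mean of this list, 0.26, was 0.387 without maltodextrin 4, where it passed, and 0.133 without maltodextrin 3. Glycolysis had a median of 0.08 (adjusted p = 0.94), with Hk2, hexokinase 2, at -1.51. Fatty acid synthesis had a median of 0.10 (adjusted p = 0.948), with Elovl6, a fatty acid elongase, higher by 1.55 and Scd1, a desaturase, at -1.02 (-0.67 without maltodextrin 4). Fatty acid oxidation (median 0.19) and cholesterol synthesis (median 0.24) each had an adjusted p = 0.0569, but passed with single arrays left out. Fatty acid oxidation passed without maltodextrin 4 or control 2, its relative mean of 0.428 being 0.652 without maltodextrin 4 and 0.205 without maltodextrin 3. Cholesterol synthesis passed without control 2 or maltodextrin 3, with relative means of 0.284 and 0.244 against 0.222 with all arrays. That mean was 0.048 with quantile normalization applied again (camera adjusted p = 0.74) and 0.077 with a mean log2 of at least 5 (camera adjusted p = 0.554). Oxidative phosphorylation (median 0.17) had an adjusted p = 0.403. Tight junction genes had a median of -0.02 (adjusted p = 0.948), although Cldn15 was higher by 2.04 and Cldn1 by 1.70. The p38 and stress kinase list had a median of 0.23 (adjusted p = 0.0569) and was the 1 list past the threshold by fry (adjusted p = 0.0398), with Mapk14, p38 alpha, higher by 0.62 (0.37 without control 2). By camera this list passed in 0 of 11 settings. Its relative mean, 0.238, was 0.093 with a mean log2 of at least 5 and 0.063 with quantile normalization applied again. The antimicrobial list did not pass (adjusted p = 0.94), with Reg3g at 10.38 on maltodextrin 3 and 3.47 on maltodextrin 4. Median, mean and camera direction differed in sign for 5 lists, which were antimicrobial defence, glycolysis, fatty acid synthesis, tight junction and absorptive colonocyte.

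Genes that mark tissue content set single arrays apart. Pancreatic acinar genes were lower as a list (median -2.09 over 16 members, camera adjusted p = 0.00516; adjusted p = 0.737 with an estimated correlation), with a median of 9.12 on control 2 and 4.71 on control 1. Without control 2 the list did not pass (adjusted p = 0.515), its mean relative to other genes being -0.118 against -1.772 with all arrays. Hoxb13 and Hoxd13, transcription factors of the distal hindgut, were 3.78 and 3.97 on maltodextrin 3 and at least 8.18 and 8.65 on the other arrays. Small nucleolar and Cajal body RNAs with Snor and Scarna names had medians of 7.51 and 9.76 on control 1 and control 2 and of 6.97 and 6.88 on maltodextrin 3 and maltodextrin 4, with 46 of 116 lower and 1 higher at the nominal criterion.

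**Figure D3:**
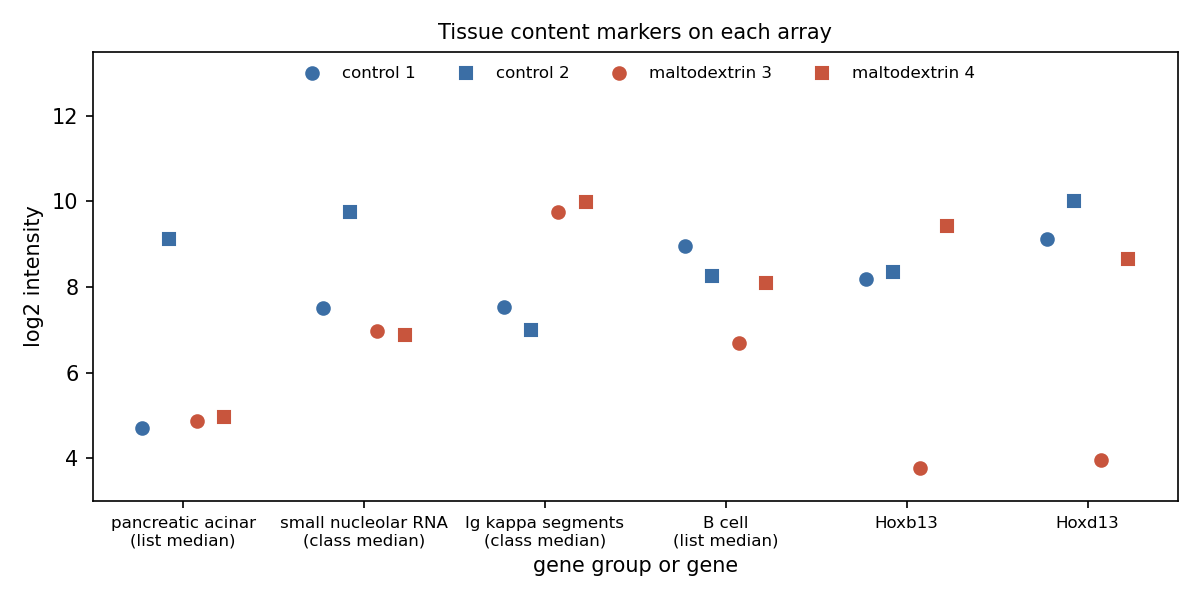
Log2 intensity (y axis) on each of the 4 arrays for 3 list or class medians of tissue markers, the small nucleolar RNA median and both distal Hox genes (x axis), with control arrays in blue and maltodextrin arrays in red. Control 2 stands apart in pancreatic genes (9.12), and maltodextrin 3 in Hoxb13 (3.78) and Hoxd13 (3.97).

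The authors' deposited table holds 1677 rows at a fold of at least 1.5 and an unadjusted p under 0.05, 1285 higher and 392 lower. Of its step-up p-values 0 were under 0.05, with a smallest of 0.0854. The 1615 of these rows with a gene symbol all met the nominal criterion by limma, which added 2272 more. In the authors' deposited table Ern2 had a fold of 2.53 (p = 0.0145), Xbp1 of 2.17 (p = 0.0202), Atoh1 of 4.65 (p = 0.0321), and Atf6, another ER stress sensor, of 1.57 (p = 0.0164).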

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

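All tests of explanations in this part were chosen after the result was seen. Of the 7552 probe sets outside the named comparison, 527 were higher on the maltodextrin arrays and 507 lower at a fold of at least 1.5 and an unadjusted p under 0.05, and 0 had an adjusted p under 0.05 by limma with 1087 at an unadjusted p under 0.05. That is 6.98% higher and 6.71% lower, against 8.06% and 3.25% of the named probe sets in the same fit. These probe sets carry no gene name here.

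More probe sets met the nominal criterion in the real grouping (3887) than in either other split of the arrays (highest 437). Of the 3 splits, 1 gave a count as large, and 3 splits are too few for a share under 0.05. The other splits also mix the groups, so a group difference would itself lower their counts.

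Small nucleolar RNA probe sets were lower on the maltodextrin arrays, with a median log2 difference of -1.48. The small nucleolar minus receptor difference was -1.15 (bootstrap interval -1.38 to -0.88, drawn over probe sets, so it does not cover the spread between arrays). Receptor medians were 3.97 on control 1, 3.38 on control 2, 3.31 on maltodextrin 3 and 3.29 on maltodextrin 4. Small nucleolar RNA medians were 7.51, 9.76, 6.97 and 6.88 in the same order. A lower background on the maltodextrin arrays is thus argued against for the gap to control 2 alone. For the gap to control 1 it stays open, since the receptor median was lower there too. A difference in the recovery of short RNAs between preparations stays open. The median difference, maltodextrin minus control, was -1.07 for mitochondrial tRNA and -0.34 for mitochondrial mRNA and rRNA, a gap of -0.72. Only 2 such mRNA and rRNA genes were measured, too few to decide. An effect of maltodextrin cannot be told apart from the preparation, and the 2 controls themselves differed by a median of 1.32.

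Maltodextrin 3 lacked Hoxb13 and Hoxd13 signal and stood above the other arrays in Reg3b, Osr2 and Isx (names chosen after their values were seen). A more proximal stretch of colon was first tested on Hoxb13 and Hoxd13 themselves, a test that could not have failed because they define the pattern, so it was replaced by the 6 other Hox genes of paralog groups 10 to 13 with a mean log2 of at least 5. Their median difference between maltodextrin 3 and 4 was 0.35, at percentile 99.21 of matched random lists. The test had assumed that a proximal stretch gives a low percentile. However, 2 were lower, Hoxa13 by 0.70 and Hoxd12 by 0.69, and 4 higher, namely Hoxa10, Hoxa11, Hoxd10 and Hoxd11. A proximal stretch thus stays open. A rule added after the values were seen says that a test decides nothing where over 25% of its members go the lesser way. Outside the test, Hoxb3 to Hoxb9, also chosen after their values were seen, were higher on maltodextrin 3 than on 4 by 1.07 to 2.48. Small intestinal tissue also stays open. A first test on Apoa1, Apoa4, Apob, Apoc3, Fabp6 and Lct spoke against it, and was replaced after its result was seen. These 6 were higher on maltodextrin 3 than on 4 by at most 0.64, with Apoa1 at 5.17 and 5.27. Apoa1, Fabp6 and Lct lay below the receptor 95th percentile. The replacing test took the whole list fixed beforehand. Its 16 genes differed by a median of 0.167 (bootstrap interval -0.098 to 0.632), 9 higher and 7 lower on maltodextrin 3. Alpi was higher by 3.99 and Sis by 1.37 and Slc15a1 lower by 1.52, and the 8 above the receptor level gave an interval of -0.026 to 1.43. Outside the list Fabp2 was higher by 2.98. A difference in response between animals cannot be told apart from tissue sampling. Of all named probe sets, 658 were over 1 log2 unit apart between the maltodextrin arrays (88 of the nominal ones, which are selected for small spread) and 2846 between the controls.

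The ER stress list was higher on the maltodextrin arrays. That only Ern2, Xbp1 and Derl3, tied to goblet or plasma cells, carry it is argued against under the preset correlation, since the other 30 members still gave camera p = 2.33e-05 with a median of 0.43, but p = 0.129 with an estimated correlation. Whether pancreatic RNA on control 2 hides part of the difference stays open: the median of 13 chaperones and isomerases was 0.30 higher on control 2 than on control 1, at percentile 97.38 of matched random lists, but 4 of the 13 were lower on it, which leaves it undecided by the same rule, and their difference was 0.48 against control 1 alone and 0.33 against both controls. An effect of maltodextrin and a change in the share of secretory cells both stay open.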

How the results depend on the processing

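Uniquely hybridising probe sets and control 1 against maltodextrin 4 alone were settings chosen after the data were seen. The count of 0 past the adjusted threshold by limma was 0 in each alternative with all 4 arrays, and ranged from 0 to 905 with 1 array left out. The nominal count of 3887 (2739 higher, 1148 lower) became 1615 (1261 and 354) by the methods' t-test and likewise with the authors' deposited fold and p, 1394 (957 and 437) at a fold of at least 2, and ranged from 1288 to 6894 with 1 array left out (973 to 3860 higher, 315 to 3903 lower). Without control 2 the excess of higher turned around (2991 higher, 3903 lower). With a mean log2 of at least 5 the lower count was 564, where fewer probe sets were tested. Of the 12 ER stress and mucus genes 5 had an unadjusted p under 0.05 by limma, against 2 by the methods' t-test and 2 to 7 with 1 array left out. The 16 lists past the threshold became 0 with an estimated correlation, which also called no simulated list shift. By fry, which tests another question, 0 of the 16 passed and 1 other list did. Leaving out 1 array ended some of the 16 calls and brought in other lists. The 11 settings that keep the preset correlation include the main fit, and eBayes with trend and robust settings, which repeats it for lists. Of the 16, the ER stress, goblet, plasma cell and macrophage lists passed in all 11 settings that keep the preset correlation, and 9 of the 16 passed with a mean log2 of at least 5, which ended the stem, proliferation, enteroendocrine, tuft, neutrophil and mast cell, fibroblast and xenobiotic calls. Quantile normalization applied again ended the stem, proliferation and fibroblast calls, and uniquely hybridising probe sets the proliferation call. MHC class II, not among the 16, passed in 4 of the 11, its relative mean ranging from -0.619 to -0.006 with 1 array left out, and the immediate early, heat shock and ribosomal lists passed in 3 each, the fatty acid oxidation, cholesterol, and T and NK cell lists in 2 each, and the sugar, circadian, deep crypt, enteric neuron, endothelium and bile acid lists in 1 each. No list passed the threshold in the opposite direction. Relative to other genes, the lists whose sign turned with 1 array left out ranged as follows: epithelial antimicrobial defence -0.022 to 0.431, interferon response -0.721 to 0.021, glycolysis -0.093 to 0.042, fatty acid synthesis -0.172 to 0.014, oxidative phosphorylation -0.07 to 0.188, tight junction and adhesion -0.027 to 0.168, circadian clock -0.039 to 0.333, absorptive colonocyte -0.076 to 0.178, deep crypt secretory and Paneth-like -0.054 to 0.513, sex-linked genes -0.093 to 0.063 and bile acid and nuclear receptor targets -0.078 to 0.626. The named genes whose sign turned so ranged as follows: Hspa5 -0.19 to 0.338, Ddit3 -0.311 to 0.033, Fcgbp -0.33 to 0.65, Clca1 -0.305 to 0.534, Saa1 -3.58 to 0.113, Reg3b -0.313 to 6.99, Iigp1 -2.93 to 0.215, Igtp -2.41 to 0.099, Ndufa4 -1.37 to 0.031, Jund -2.08 to 0.041, Hsph1 -1.29 to 0.212, Slc51a -0.295 to 4.22, Aurkb -0.008 to 1.42, Bub1 -0.165 to 1.21, Nts -0.195 to 3.12, Reg4 -3.92 to 0.841, Mmp7 -0.147 to 1.83, Hoxb13 -4.49 to 1.17, Slc15a1 -1.45 to 0.07, Ddx3y -0.294 to 0.082, Xist -0.218 to 0.356, S100g -0.189 to 1.98 and Slc51b -0.531 to 1.63. The sign also turned with a mean log2 of at least 5 for oxidative phosphorylation -0.086, tight junction and adhesion -0.104 and absorptive colonocyte -0.094, and with quantile normalization applied again for oxidative phosphorylation -0.082, tight junction and adhesion -0.069, circadian clock -0.001, absorptive colonocyte -0.043, sex-linked genes 0.073, Hspa5 -0.102 and Ddx3y 0.047. Of 1823 gene values over the alternatives 1796 kept their sign. Settings that only filter probe sets or change the test leave a gene's difference as it was, so those values could not turn. Most of these genes were also named for large differences on the same arrays. On control 1 against maltodextrin 4 alone, a value with no test, the relative mean was 0.709 for ER stress, 0.967 for goblet and 1.35 for plasma cell genes, but -0.443 for B cell, -0.861 for interferon and -0.011 for pancreatic genes. The authors' deposited list with a symbol lay wholly within the nominal set at 100%. A mean log2 of at least 5 takes only a part of that list, so it had to give 100% too. Where no construction is named, the cause was not tested. No paired analysis was possible because the groups share no sample number.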

Other observations

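Immunoglobulin segments were among the most shifted classes. Of 95 heavy chain segments 59 were higher and 0 lower at the nominal criterion, with a median of 1.69, and of 93 kappa segments 65 were higher and 0 lower, with a median of 2.13. Igh-VS107 was higher by 4.81 and Ighv3-8 by 4.01, while Igkv7-33 was 7.37 on maltodextrin 3 and 13.13 on maltodextrin 4. None passed an adjusted p of 0.05 by limma. Among T cell receptor segments 8 of 188 were higher and 9 lower, and the gamma segments Tcrg-V4 at 2.59 and Tcrg-C2 at 2.37 stood among the largest, names chosen after their values were seen.

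Zinc finger genes named Zfp, of which the authors' second sheet lists 35, were higher in 69 and lower in 2 of 366 cases at the nominal criterion, which is 18.9% higher against 8.58% of other genes. Their median difference was 0.28. The contrast was not matched on brightness, since the other genes include 6778 predicted Gm genes, 1.67% of them higher. Of 17845 named probe sets with a mean log2 of at least 5, 2490 were higher at the nominal criterion. Zfp953 was higher by 1.88. The authors' list was chosen on these samples and is not independent evidence of the direction. Mitochondrial tRNA genes were below 0 in 18 of 18, and 12 met the nominal criterion. Olfactory receptors were lower in 82 of 1120 and higher in 1, with medians of 4.02 on control 1 and 3.41 on control 2. The sign of the median of these classes was the same with quantile normalization applied again (0.23 for Zfp genes, -0.19 for olfactory receptors) and with arrays centred on their medians.

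Immediate early genes did not pass by camera (adjusted p = 0.24), with Fos at -1.66 (-1.07 without control 2) and Atf3 at -1.58. The heat shock list (adjusted p = 0.151), circadian clock list (adjusted p = 0.122), ribosomal protein list (adjusted p = 0.0874), endothelium list (adjusted p = 0.0569), enteric neuron and glia list (adjusted p = 0.104), bile acid and nuclear receptor list (adjusted p = 0.355), small intestinal list (adjusted p = 0.667), posterior Hox list (adjusted p = 0.838) and sex-linked list (adjusted p = 0.948) did not pass either. The immediate early, heat shock and ribosomal lists, lower relative to other genes, each passed in 3 of 11 settings, among them quantile normalization applied again (adjusted p = 0.0277, 0.00641 and 0.014) and a mean log2 of at least 5 (adjusted p = 0.0211, 0.0164 and 0.00524). Their relative means, -0.271, -0.255 and -0.211, were -0.092, -0.001 and -0.032 without control 2, so the lower direction rested largely on that array. Hspa1a differed by -1.13 (-0.72 without control 2), Per3 by 0.73 and Emcn, an endothelial sialomucin, by 1.26 (0.78 without control 2).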
